A study of Mus musculus with 18 samples.

How the data were processed

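Deposited counts of 18 RNA-seq libraries were analysed. The libraries fall into 6 groups of 3, from 3 sorted subsets of osterix-derived cells of control mice and of mice with a conditional knockout of Pth1r, at postnatal day 21. Per the labels' protocols, RNA was taken with an RNeasy Plus Micro kit, cDNA was made with SMART-Seq v4 chemistry for low input and libraries with SMARTer ThruPLEX reagents. The values are raw read counts per gene made by the authors with featureCounts, per the file headers, with the length of the merged exons of each gene beside them. The submitters' processing notes name mm10, STAR, featureCounts and DESeq2 and give no versions. Whether counting used strand and how reads with several matches were treated is not given in the sources used here, so genes with near-identical copies, overlapping genes and antisense partners are uncertain. The labels do not say whether libraries of a group came from separate animals, so p-values measure the spread between these samples. By Y-linked genes, only replicates 1 and 2 could be technical repeats. Libraries of a group differed in every pair by more than sampling noise (chi-square per degree of freedom 14.9 to 55.9), and none was merged.

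The labels give the libraries of each group the numbers 1 to 3. Whether same-number libraries deviate together from their group means was checked for the groups of each comparison. Between subsets of the controls all 9 correlations were over 0.1, from 0.15 to 0.249 between the bone subsets, from 0.195 to 0.259 between GFP-negative bone and marrow and from 0.101 to 0.177 between GFP-positive bone and marrow (at least 0.082 there on autosomal genes alone). Between subsets of the knockouts they ran from 0.17 to 0.362. The numbers were therefore taken to pair the subsets within a genotype, on the evidence of the data and not of the labels. Between knockout and control of a subset 2 of 9 were over 0.1, and the numbers were not taken to pair them. This was settled comparison by comparison after results with a block had been seen.

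Total counts per library ran from 16443595 to 27160257. A gene with a count of 0 may be present at up to 3 counts per library, 0.097 to 0.216 CPM after TMM scaling. A fold against a group at 0 uses the highest such floor of its 3 libraries. Such floors and any counting interval cover counting error only, since the reads carry no molecular identifiers. The files hold 54446 gene IDs, of which 54409 matched a symbol in a mouse annotation of mm10 and 53229 also matched its version number. Coordinates and transcript lengths come from that annotation, on build mm10, and sequence was used only for the GC content of transcripts.

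Groups were taken from the titles and genotype labels. The comparisons, tests, gene lists, naming rule and other settings to try were fixed before the data were examined. All 18 libraries were fitted in 1 model with a mean for each of the 6 groups (12 residual degrees of freedom) with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr by group (minimum count 10, minimum total 15), which left 15516. Libraries were scaled by TMM, and the quasi-likelihood F-test was run with robust estimation. The common dispersion was 0.02 and the median prior degrees of freedom 6.63. Tests are two-sided, with Benjamini-Hochberg (BH) adjustment over all genes and a threshold of 0.05. The SE of a log2 fold change is its size divided by the square root of F, an approximation. It can be too small where 1 group has few counts. The 9 comparisons are knockout against control in each subset, the difference of the knockout effect between each pair of subsets, and each pair of subsets in controls. No covariate was used, so these tests leave out the pairing of same-number libraries between subsets of a genotype. Results with the replicate number as a block are given separately. Levels of single genes are CPM of the library total after TMM scaling, and sums over marker, megakaryocyte and Y-linked genes are CPM of the library total itself, as mean ± SD over 3 libraries.

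Of 27 fixed gene lists, 16 cover bone, cartilage, stroma, fat, signalling and metabolism and 11 hold markers of other cell types. The 25 lists with at least 4 measured genes were tested with edgeR camera (preset correlation 0.01, two-sided, BH over the lists). Dispersions for camera came from a separate estimateDisp step. Camera was also run with a correlation estimated from the data. The lists overlap in part. List tests of the interaction comparisons were added after the data were seen. The text names Pth1r, then genes past 0.05 with a mean of at least 5 CPM in the higher group and no overlap between the groups' 3 libraries, taken from the 10 largest rises and 10 largest falls per knockout comparison and the 6 largest on each side per control comparison. It also names up to 4 members per list with the smallest p and the 5 interaction genes with the smallest p. Bare gene models, -ps, mt- and Rik names were left out of the naming. Not all genes that the rule yields are named, and some are not reported here. Col2a1 in all comparisons, and the 4 genes plotted by subset, were chosen after their values were seen.

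The settings chosen then were DESeq2 1.42.0 (Wald test), limma 3.58.1 voom with sample quality weights, RLE scaling, no filter on low counts, robust estimation off, only the libraries compared, the replicate number as a block, each library left out in turn, and for lists the estimated correlation and the fry test. Chosen after seeing the data were a correction for transcript length, the same correction with the exon length of the count files, library totals without scaling factors, and a test against a 1.5-fold change (edgeR glmTreat), and the replicate number as a block within each genotype. The length correction takes each gene's log2 CPM minus its mean over all 18 libraries (prior count 2), fits a lowess on log2 length in each library (span 0.3, 3 iterations) and enters it as an offset. The longest transcript was preferred to the exon length of the count files after it was seen to follow the fold changes more closely. Length, exon length and GC content were examined.

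The gene tests were checked on counts simulated from the real means and library sizes over 14781 genes. Few were changed, 132 to 134 per fold between 2 groups. In the simulated marrow, GFP-positive and GFP-negative bone comparisons of knockout with control, 98.5, 99.2 and 98.5% of 4-fold changes, 37.3, 47.8 and 47.0% of 2-fold changes and 5.2, 6.7 and 5.2% of 1.5-fold changes were recovered, and 5.6, 3.3 and 6.1% of calls were false. For the interaction of GFP-positive with GFP-negative bone 89.4% of 4-fold and 25.0% of 2-fold changes were recovered, for GFP-negative bone with marrow 90.2 and 11.9%, and for GFP-positive bone with marrow 92.4 and 18.7%. For controls these were 98.5 and 44.8% between the bone subsets. They were 98.5 and 41.0% between GFP-negative bone and marrow, and 100 and 41.8% between GFP-positive bone and marrow. No list of 25 was called by camera in any of the 6 simulated comparisons, and at an unadjusted p under 0.05 there was 1, in GFP-positive bone. The simulated genes were independent and no list gene was changed, so this does not show how often camera calls lists of correlated genes. When a length trend was added to the simulated libraries (14531 genes), 66.3, 64.9 and 66.2% of the calls in the 3 knockout comparisons were false without the correction, and 3.2, 6.3 and 4.2% with it (14526 genes). Tables and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.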

Results

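RNA was profiled in osterix-derived cells sorted from mice at postnatal day 21. Osterix is a transcription factor of the bone-forming lineage. Cells came from control mice and from mice with a conditional knockout of Pth1r, the receptor for parathyroid hormone and for parathyroid hormone-related protein. Each genotype was sorted into 3 subsets by GFP and by a marker that the labels write as Tm. The marrow subset was GFP-negative and Tm-positive, and its cells were bone marrow stromal cells. Both other subsets were bone cells, 1 of them GFP-positive and the other GFP-negative and Tm-positive. They are called the GFP-positive bone subset and the GFP-negative bone subset. Each of the 6 groups had 3 libraries, 18 in all. Between 18486 and 20237 genes had at least 1 count in a library, and a count of 0 allowed up to 0.097 to 0.216 CPM (counts scaled to a common library total after TMM scaling), depending on the library. All values below are means ± SD in CPM (n = 3 per group) or log2 fold changes ± SE of knockout over control (n = 3 against 3). The first 3 principal components held 60.0, 19.0 and 9.80% of the variance. The first separated the subsets and the second the genotypes.

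Pth1r (ENSMUSG00000032492.14; mm10 chromosome 9, 110722085 to 110747145, minus strand) was lower in every knockout library than in every control library of its subset, and it was still counted in all of them. In the marrow subset the 3 control libraries held 541, 581 and 553 CPM and the 3 knockout libraries 373, 337 and 318 CPM. In the GFP-positive bone subset the controls held 4481, 4842 and 5035 CPM and the knockouts 4038, 3255 and 2725 CPM. In the GFP-negative bone subset the values were 1674, 1669 and 1911 CPM against 1398, 1137 and 1031 CPM. The log2 fold changes were -0.70 ± 0.13 in marrow, -0.52 ± 0.13 in the GFP-positive and -0.56 ± 0.13 in the GFP-negative bone subset. These are 1.63-, 1.43- and 1.47-fold lower levels (edgeR quasi-likelihood test, BH-adjusted p = 1.95e-04, 2.26e-03 and 1.44e-03). After a correction for transcript length, described with the length trend, the fall was -0.43 ± 0.12 in marrow, and the call ended in both bone subsets, at -0.22 ± 0.12 and -0.24 ± 0.12 (edgeR adjusted p = 0.00864, 0.157 and 0.125). The counts cover all exons of the gene, so a transcript that lacks the deleted part is still counted.

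**Figure D1:**
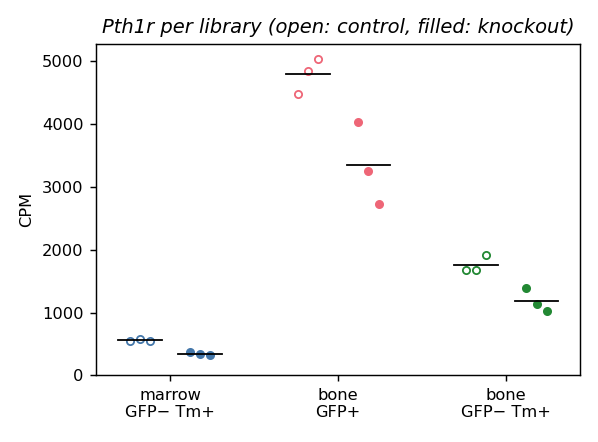
Pth1r in CPM in each of the 18 libraries, by subset, with open points for control, filled points for knockout and a line at the mean of 3. Group means were 558 and 343 CPM in marrow, 4790 and 3340 CPM in the GFP-positive bone subset, and 1750 and 1190 CPM in the GFP-negative bone subset, control first.

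Fold changes in the knockout followed transcript length in all 3 subsets. Across 15511 genes with a length, the Spearman correlation of the log2 fold change with the length of the longest transcript was 0.41 in marrow, 0.44 in the GFP-positive and 0.44 in the GFP-negative bone subset. Genes are not independent replicates, and no p is given. The decile with the shortest transcripts (median 770 bases) had median log2 fold changes of -0.54, -0.43 and -0.59. The decile with the longest (8099 bases) had 0.83, 1.25 and 0.91. Each library's deviation from its subset mean was regressed on length. Slopes were 0.143 to 0.218 per doubling in the 9 knockout and -0.233 to -0.131 in the 9 control libraries. By this centring the genotypes mirror each other. Fitting and removing the trend in each library lowered the correlations to 0.02, 0.03 and 0.02. The trend moves with genotype in every subset, and corrected values are given where they change a call.

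**Figure D2:**
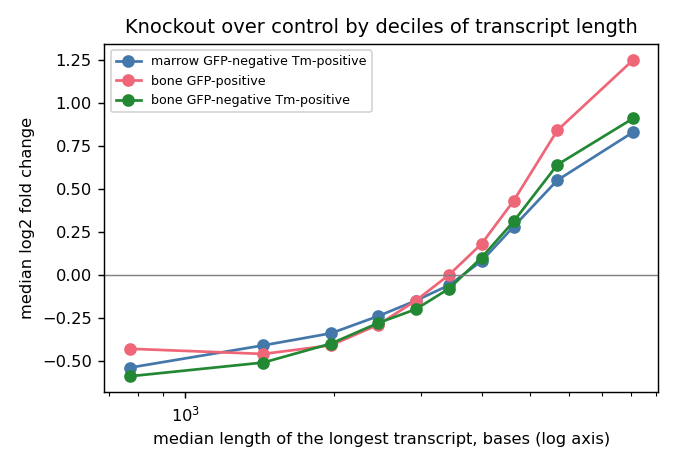
Median log2 fold change of knockout over control (vertical axis) for deciles of the tested genes ordered by transcript length (horizontal log axis, median length in bases), with 1 line per subset. From the shortest to the longest decile the median went from -0.54 to 0.83 in marrow, from -0.43 to 1.25 in the GFP-positive and from -0.59 to 0.91 in the GFP-negative bone subset.

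In marrow stromal cells, knockout was compared with control to ask what loss of the receptor does in this subset. Fat-cell and stromal genes were higher in the knockout, and genes of bone formation, cell division and respiration were lower. Of these list calls only that of the fat-cell genes held with an estimated correlation, where the camera adjusted p was 0.22 for stroma, 0.291 for osteoblast and cell cycle and 0.248 for oxidative phosphorylation genes. Plin1, which coats lipid droplets (mm10 chromosome 7, 79720218 to 79732903), rose from 5.40 ± 0.82 to 69.6 ± 16.9 CPM, 12.9-fold. Bglap, which encodes the bone matrix protein osteocalcin, fell from 3030 ± 1220 to 463 ± 102 CPM, 6.55-fold lower. Among the largest rises by the naming rule were AI506816 (6.59 ± 0.18), a processed transcript, Zdhhc23 (5.42 ± 0.52), a protein palmitoyltransferase, Hif3a (5.02 ± 0.42), a hypoxia-inducible factor subunit, Klb (4.55 ± 0.44), the FGF21 co-receptor, and Zbtb16 (3.72 ± 0.37), a zinc finger transcription factor. Among the largest falls were Cnn1 (-5.00 ± 0.98), Actg2 (-4.30 ± 0.28) and Acta2 (-3.96 ± 0.53), which encode contractile proteins of smooth muscle, and Slc9a2 (-4.04 ± 0.37), a sodium-proton exchanger. The control libraries varied widely in Cnn1 (25.1 ± 32.9 CPM) and Acta2 (833 ± 731 CPM).

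The fixed lists moved apart in marrow. Of 21 adipocyte genes, 18 rose and none fell, among them Cd36 (3.65 ± 0.38), a fatty acid transporter, Acsl1 (3.23 ± 0.19), which activates fatty acids, and Zfp423 (1.61 ± 0.15), a factor of preadipocytes. Of 18 marrow stroma genes, 15 rose and none fell, such as Ebf3 (1.80 ± 0.13), Pdgfrb (1.61 ± 0.15) and Csf1 (1.46 ± 0.12), the macrophage growth factor. Of 20 osteoblast genes, 14 fell and none rose, such as Sparc (-1.44 ± 0.15) and Alpl (-1.43 ± 0.11), the alkaline phosphatase of mineralising cells. Of 11 osteocyte genes, 6 fell and 1 rose. Dkk1, a Wnt antagonist, fell by 2.84 and Pdpn by 2.52 on the log2 scale. Of 17 fibroblast and periosteal genes, 11 fell and 2 rose. Timp1, an inhibitor of matrix proteases, changed by -2.39 ± 0.15, and the proteoglycan genes Lum and Dcn by -2.30 ± 0.20 and -2.00 ± 0.20. Of 12 Wnt antagonists, 7 fell and 2 rose, with Frzb at -2.09 ± 0.17 and Sfrp4 at -2.29 ± 0.33. Adjusted over the list alone, 18 adipocyte and 15 stroma genes rose, 14 osteoblast genes fell and 1 rose, and the osteocyte, fibroblast and Wnt antagonist counts were the same as over all genes.

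The edgeR camera adjusted p was 5.32e-12 for the adipocyte list in marrow (median 1.60), 5.75e-10 for stroma (1.10), 7.39e-06 for osteoblast (-0.93), 0.0115 for osteocyte (-1.20), 8.11e-05 for fibroblast (-1.95) and 0.0119 for Wnt antagonists (-1.09). With an estimated correlation the adipocyte call held, at an adjusted p of 8.85e-05. The other 5 were lost, at camera adjusted p = 0.22 for stroma, 0.291 for osteoblast, osteocyte and fibroblast, and 0.248 for Wnt antagonists.

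Stress, signalling and metabolic lists also moved in marrow. Of 18 immediate early and heat shock genes, 15 rose and none fell (Fosb 1.77 ± 0.24). Of 20 genes that respond to cAMP and parathyroid hormone, 11 rose and 5 fell. Sik1, a kinase induced by cAMP, rose by 3.07 ± 0.29 and the clock gene Per1 by 2.77 ± 0.17, whereas the nuclear receptor gene Nr4a2 changed by -1.26 ± 0.21. Of 22 cell cycle genes, 17 fell and none rose (Cenpa -1.38 ± 0.16; Cdk1 -1.31 ± 0.19). Of 18 oxidative phosphorylation genes, 16 fell and none rose (Ndufa1 -1.22 ± 0.13). Of 16 glycolysis genes, 10 fell and 3 rose, with Pkm at -1.18 ± 0.10 and Aldoa at 0.64 ± 0.09. Adjusted over the list alone, 15 immediate early genes rose, 11 cAMP genes rose and 5 fell, 18 cell cycle genes fell and 1 rose, 17 oxidative phosphorylation genes fell, and 11 glycolysis genes fell and 3 rose. The edgeR camera adjusted p was 2.51e-05 for immediate early genes, 0.0115 for cAMP genes, 7.80e-05 for cell cycle, 2.40e-08 for oxidative phosphorylation and 0.0217 for glycolysis. All 5 were lost with an estimated correlation, at camera adjusted p = 0.318, 0.307, 0.291, 0.248 and 0.318 in that order. The glycolysis call was also lost without knockout marrow replicate 1 (camera adjusted p = 0.0538) and in a fit of only the libraries compared (0.0559).

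The 16 lists include 5 that did not pass camera in marrow. Regulators of blood cells and osteoclasts had 7 of 15 members higher and 4 lower (8 and 4 adjusted over the list alone; camera adjusted p = 0.06, but 0.0481 after the length correction, 0.00755 without control replicate 1 and 0.0167 without knockout replicate 1), with Angpt1, a ligand of the Tie2 receptor, at 1.84 ± 0.14 and Ptn, a heparin-binding growth factor, at -1.81 ± 0.21. Wnt targets had 1 of 12 higher and 6 lower (the same adjusted over the list alone; camera adjusted p = 0.06, but 0.0384 after the length correction, 0.0109 without control replicate 1 and 0.041 without knockout replicate 2). Chondrocyte genes had 5 of 19 higher and 7 lower (6 and 7 adjusted over the list alone; camera adjusted p = 0.71), p53 and apoptosis genes 7 of 20 higher and 4 lower (the same adjusted over the list alone; camera adjusted p = 0.624), and interferon genes 1 of 16 lower (the same adjusted over the list alone; camera adjusted p = 0.581, and 0.0239 without knockout replicate 2).

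In marrow as a whole 3581 of 15516 genes rose and 3844 fell, 7425 in all, and 3134 of these changed at least 2-fold, 1834 higher and 1300 lower (edgeR quasi-likelihood test, two-sided, BH-adjusted p under 0.05). Of the calls 48.2% were higher, and 59.6% when libraries were scaled by their totals alone, which moved the median gene by 0.14. The oxidative phosphorylation genes had short transcripts (median 1832 bases) and the stroma genes long ones (4517 bases). After the length correction the medians of these lists were -0.30 and 0.84, 6087 genes were called, among them 4854 (65.4%) of the 7425 in the same direction and 34 in the opposite one, and each list that had passed camera still passed with the preset correlation.

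In GFP-positive bone cells the knockout libraries held more cartilage and stroma transcripts and less of the glycolytic enzymes. The glycolysis call held with an estimated correlation, and the cartilage and stroma calls did not (camera adjusted p = 0.447 and 0.119). Acan, the main proteoglycan of cartilage (mm10 chromosome 7, 79053483 to 79115099), rose from 1470 ± 173 to 7020 ± 935 CPM, 4.79-fold. Pgk1, a glycolytic kinase, changed by -1.92 ± 0.10. AI506816 rose by 8.90 ± 0.18, the largest rise among the genes named here with counts in both groups. Nptx1, a neuronal pentraxin, was at 0 in all 3 controls and at 9.83 ± 4.74 CPM in the knockout, at least 68.1-fold higher than the highest floor of 3 counts per library in those controls. Klhl40 (7.38 ± 0.68), a protein stabiliser of muscle, Fhl3 (6.62 ± 0.38), a LIM-domain protein, Plet1 (5.97 ± 0.81) and Aqp3 (5.30 ± 0.62), a water and glycerol channel, were also higher. Ndufa4l2 (-2.87 ± 0.18) and Fam162a (-2.50 ± 0.10), both induced by hypoxia, Tnmd (-2.61 ± 0.37), a tendon protein, Atp6v0c (-2.61 ± 0.24), a proton pump subunit, and Sfrp5 (-2.18 ± 0.28), a Wnt antagonist, were lower.

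Of 19 chondrocyte genes, 12 rose and 4 fell in GFP-positive bone cells. Col11a2 (3.39 ± 0.26) and Col9a2 (1.61 ± 0.12), both cartilage collagens, rose, and Ucma, a matrix protein of cartilage, fell (-1.55 ± 0.13). Of 18 stroma genes, 16 rose and none fell, among them Pdgfrb (2.13 ± 0.17), Vcam1 (1.93 ± 0.18), an adhesion molecule, Cxcl12 (1.92 ± 0.17), the chemokine that retains blood stem cells, and Lepr (1.89 ± 0.17), the leptin receptor. Of 21 adipocyte genes, 11 rose and none fell, with Fasn, fatty acid synthase, at 3.31 ± 0.16 and Apoe at 1.93 ± 0.13. Of 11 osteocyte genes, 6 rose and none fell, with Phex, a peptidase of mineralising cells, at 2.84 ± 0.15. Of 20 cAMP and parathyroid hormone genes, 9 rose and none fell (Sik1 3.15 ± 0.36; Fosl1 2.37 ± 0.23). Of 15 regulators of blood cells and osteoclasts, 10 rose and 1 fell. Of 16 glycolysis genes, 13 fell and 3 rose, with Pgam1 at -1.70 ± 0.09, Ldha, lactate dehydrogenase, at -1.48 ± 0.09, and the lactate exporter gene Slc16a3 at -2.20 ± 0.16. Of 18 oxidative phosphorylation genes, 17 fell and none rose (Sdhb -1.11 ± 0.09; Uqcrc2 -1.06 ± 0.08). Adjusted over the list alone, 13 chondrocyte genes rose and 4 fell and 17 stroma genes rose, and the counts of the other 6 lists were the same as over all genes.

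The edgeR camera adjusted p in GFP-positive bone cells was 0.000557 for the chondrocyte list (median 0.79), 2.96e-11 for stroma (1.60), 5.57e-05 for adipocyte (1.15), 0.0116 for osteocyte (0.63), 0.0194 for cAMP (0.72), 0.00275 for regulators of blood cells (0.86), 7.76e-10 for glycolysis (-1.18) and 2.96e-11 for oxidative phosphorylation (-0.80). The adipocyte and glycolysis calls held with an estimated correlation (camera adjusted p = 0.00967 and 0.0323). The others were lost, at camera adjusted p = 0.447 for chondrocyte and cAMP, 0.119 for stroma and oxidative phosphorylation, and 0.387 for osteocyte and regulators of blood cells with an estimated correlation.

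The other 8 of the 16 lists did not pass camera in GFP-positive bone cells. Osteoblast genes had 9 of 20 members higher and 3 lower (the same adjusted over the list alone; camera adjusted p = 0.182), with Col22a1 at 2.33 ± 0.24 and Runx2, a master regulator of osteoblasts, at 0.96 ± 0.12. After the length correction Runx2 was at 0.11 ± 0.12 and no longer passed (edgeR adjusted p = 0.487). Alpl was at 0.63 ± 0.11 and lost its call with library totals alone (0.25, edgeR adjusted p = 0.0689). Cell cycle genes had 4 of 22 higher and 13 lower (4 and 16 adjusted over the list alone; camera adjusted p = 0.182), with Cenpf at 3.15 ± 0.38 and Tyms at -1.07 ± 0.15. Fibroblast genes had 5 of 17 higher and 3 lower (the same adjusted over the list alone; camera adjusted p = 0.761), with Fn1, fibronectin, at 3.30 ± 0.19 and Dpt at -3.39 ± 0.58. The fibroblast median was -0.22, the mean 0.05 and the test pointed up. Immediate early genes had 3 of 18 higher (2 adjusted over the list alone; camera adjusted p = 0.799), and Wnt targets had 2 of 12 higher and 2 lower (the same adjusted over the list alone; 0.944). Wnt antagonists had 2 of 12 higher and 1 lower (the same adjusted over the list alone; 0.944; median 0.08, mean -0.24, test up), with Kremen1 at 1.34 ± 0.15. The p53 genes had 8 of 20 higher and 3 lower (the same adjusted over the list alone; 0.944), and interferon genes 2 of 16 higher and 1 lower (2 and 0 adjusted over the list alone; 0.944).

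In GFP-positive bone cells 4034 genes rose and 3919 fell, 7953 in all, of which 3626 changed at least 2-fold, 2627 higher and 999 lower (edgeR quasi-likelihood test, two-sided, BH-adjusted p under 0.05). The share of calls that were higher was 50.7%, and 30.9% with library totals alone, a scaling that moved the median gene by -0.38. The 10 most abundant genes took 23.3 ± 0.62% of the counts in controls and 37.4 ± 0.70% in knockouts. Col2a1, the main cartilage collagen, rose from 84700 ± 11200 to 264000 ± 14600 CPM there. Col2a1 was chosen after its values were seen. With the length trend removed 6559 genes were called, among them 5350 (67.3%) of the 7953 in the same direction and 80 in the opposite one, the medians were 1.26 for stroma and -0.51 for oxidative phosphorylation, and each list that had passed camera still passed with the preset correlation.

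In GFP-negative bone cells stroma and fat-cell genes were again higher in the knockout, whereas cartilage, cell cycle and glycolysis genes were lower. The cartilage and cell cycle calls were lost with an estimated correlation (camera adjusted p = 0.15 and 0.11), and the other 3 held. Ucma fell from 67.6 ± 7.43 to 7.88 ± 1.74 CPM, 8.61-fold lower (mm10 chromosome 2, 4976122 to 4985748). Lepr rose from 91.8 ± 14.2 to 364 ± 11.6 CPM, a log2 change of 1.99 ± 0.16. AI506816 rose by 7.94 ± 0.18, Pappa2, a protease of IGF-binding proteins, by 4.94 ± 0.60, Fhl3 by 4.40 ± 0.52, Timp4 by 4.18 ± 0.43, Acacb, an acetyl-CoA carboxylase, by 4.02 ± 0.44, and Zbtb16 by 3.61 ± 0.53. The Wnt antagonist gene Sfrp5 (-4.19 ± 0.50), the BAFF receptor gene Tnfrsf13c (-3.40 ± 0.43), C1qtnf3 (-3.05 ± 0.13) and Slc16a3 (-3.02 ± 0.19) were lower.

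All 18 stroma genes rose in GFP-negative bone cells, among them Pdgfra (2.13 ± 0.13), Pdgfrb (1.90 ± 0.15) and Csf1 (1.46 ± 0.13). Of 21 adipocyte genes, 15 rose and none fell, with Fasn at 1.65 ± 0.16, Lpl, lipoprotein lipase, at 1.64 ± 0.16 and Cebpa at 1.63 ± 0.20. Of 15 regulators of blood cells and osteoclasts, 9 rose and 1 fell (Angpt1 2.21 ± 0.16). Of 20 cAMP and parathyroid hormone genes, 10 rose and 1 fell (Sik1 2.73 ± 0.37; Per1 1.82 ± 0.18). Of 20 osteoblast genes, 9 rose and 1 fell, with Col22a1 at 2.50 ± 0.22, Col1a2 at 1.15 ± 0.19 and Runx2 at 0.86 ± 0.12. Col1a2 lost its call when the length correction used the exon length of the count files (edgeR adjusted p = 0.0561). With the length correction Runx2 was at 0.16 ± 0.12 and no longer passed (edgeR adjusted p = 0.352). Of 19 chondrocyte genes, 12 fell and 2 rose, with Cnmd, chondromodulin, at -2.40 ± 0.14, Matn3 at -2.16 ± 0.13 and Hapln1 at -1.59 ± 0.12. Of 22 cell cycle genes, 20 fell and none rose (Cdk1 -2.11 ± 0.20; Ccnb1 -1.84 ± 0.20). Of 16 glycolysis genes, 13 fell and 2 rose (Pgk1 -1.93 ± 0.10; Pgam1 -1.77 ± 0.09). All 18 oxidative phosphorylation genes fell, with Cycs, cytochrome c, at -1.16 ± 0.10. Adjusted over the list alone 14 glycolysis genes fell and 2 rose, and the counts of the other 8 lists were the same as over all genes.

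The edgeR camera adjusted p in GFP-negative bone cells was 2.45e-16 for stroma (median 1.52), 2.22e-06 for adipocyte (1.08), 7.27e-05 for regulators of blood cells (0.97), 0.0458 for cAMP (0.51), 0.0458 for osteoblast (0.27), 5.18e-07 for chondrocyte (-0.70), 2.82e-09 for cell cycle (-1.53), 6.62e-14 for glycolysis (-1.35) and 2.90e-12 for oxidative phosphorylation (-0.91). The stroma, adipocyte and glycolysis calls held with an estimated correlation (camera adjusted p = 0.0343, 0.00344 and 0.0103). The other 6 were lost, at camera adjusted p = 0.144 for regulators of blood cells, 0.556 for cAMP, 0.916 for osteoblast, 0.15 for chondrocyte, 0.11 for cell cycle and 0.108 for oxidative phosphorylation with an estimated correlation. The osteoblast call was also lost without control replicate 1, knockout replicate 1 or knockout replicate 3 (camera adjusted p = 0.0814, 0.0562 and 0.0777). The cAMP call was lost without control replicate 1 or 2 or knockout replicate 2 or 3 (camera adjusted p = 0.0503, 0.0753, 0.0555 and 0.0554), and with RLE factors (0.0535).

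The other 7 of the 16 lists did not pass camera in GFP-negative bone cells. Osteocyte genes had 3 of 11 members higher and 4 lower (the same adjusted over the list alone; camera adjusted p = 0.928), with Phex at 1.41 ± 0.13 and Dkk1 at -1.60 ± 0.22. The osteocyte median was -0.01, the mean -0.04 and the test pointed up. Fibroblast genes had 5 of 17 higher and 4 lower (the same adjusted over the list alone; 0.444), with Fn1 at 2.42 ± 0.18. Wnt antagonists had 3 of 12 higher and 4 lower (the same adjusted over the list alone; 0.928), with Kremen1 at 1.83 ± 0.15. Immediate early genes had 5 of 18 higher and 1 lower (the same adjusted over the list alone; camera adjusted p = 0.46, but 0.0413 after the length correction), Wnt targets 3 of 12 higher and 2 lower (the same adjusted over the list alone; 0.928), p53 genes 5 of 20 higher and 6 lower (5 and 7 adjusted over the list alone; 0.928), and interferon genes 1 of 16 higher (0 adjusted over the list alone; 0.928).

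In GFP-negative bone cells 3335 genes rose and 3980 fell, 7315 in all, of which 3022 changed at least 2-fold, 1843 higher and 1179 lower (edgeR quasi-likelihood test, two-sided, BH-adjusted p under 0.05). The share of calls that were higher was 45.6%, and 30.8% with library totals alone, which moved the median gene by -0.24. It was 53.1% with RLE factors and 52.9% with DESeq2, so which side held more genes depended on the scaling. With those totals the osteoblast list had 7 members higher and 4 lower, with a median of 0.02. With the length trend removed 5821 genes were called, among them 4610 (63%) of the 7315 in the same direction and 29 in the opposite one, the medians were 1.46 for stroma and -0.44 for oxidative phosphorylation, and each list that had passed camera still passed with the preset correlation.

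**Figure D3:**
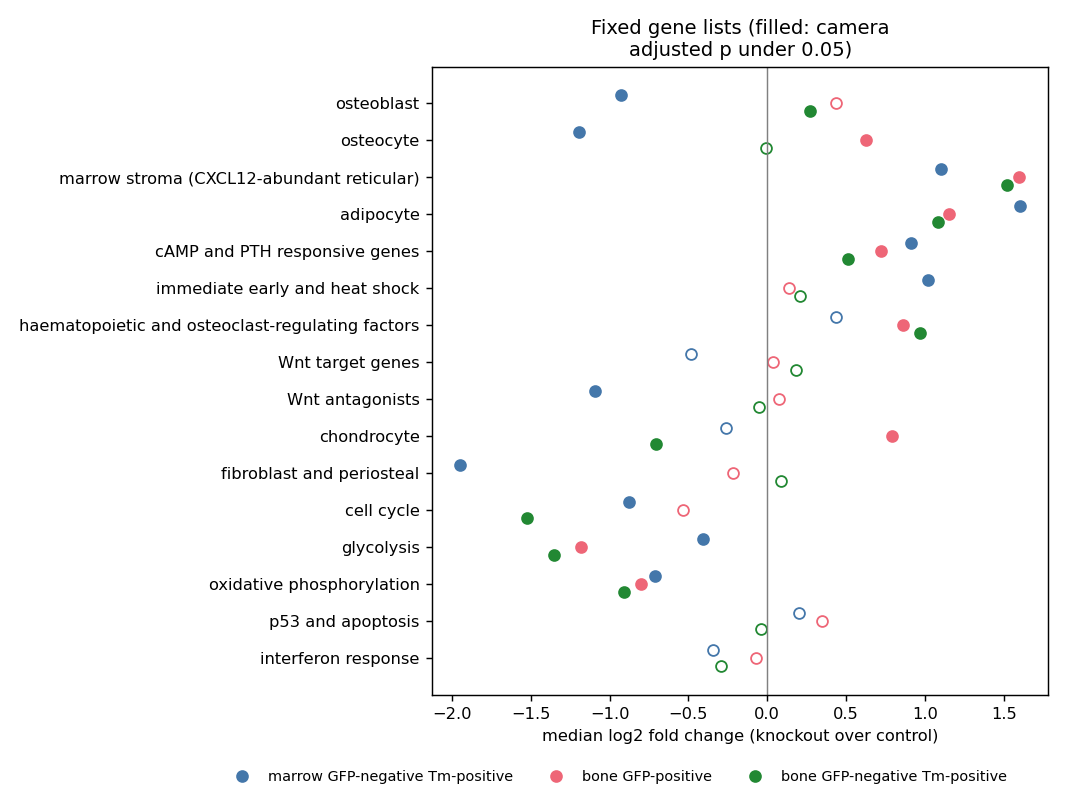
Median log2 fold change of knockout over control (horizontal axis) for the 16 fixed gene lists (vertical axis) in each subset, with filled points where the camera adjusted p was under 0.05. Stroma genes had medians of 1.10 in marrow, 1.60 in the GFP-positive and 1.52 in the GFP-negative bone subset, and oxidative phosphorylation genes -0.71, -0.80 and -0.91.

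In all 3 subsets 1947 genes rose and 2169 fell, against 200.1 and 249 for independent lists of these sizes. The 3 comparisons share no libraries, but same-number libraries pair across subsets within a genotype and the length trend is in all 3. The value for independent lists takes no account of either, so the excess is not read as a shared effect. Across genes, which are not independent, the Pearson correlation of the fold changes was 0.43 between marrow and the GFP-positive bone subset, 0.55 between marrow and the GFP-negative bone subset and 0.59 between the bone subsets. With the length trend removed the correlations were 0.34, 0.48 and 0.51. Notch3, a pericyte receptor gene, rose in each of the 3, by 2.28 ± 0.27 in marrow, 3.36 ± 0.51 in GFP-positive and 2.83 ± 0.31 in GFP-negative bone cells.

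Markers of other cell types were measured beside these groups. The Schwann cell list passed in marrow, with 4 of 6 members lower (the same adjusted over the list alone; median -1.41; camera adjusted p = 0.0366), and was lost at camera adjusted p = 0.248 with an estimated correlation and without control or knockout marrow replicate 3 (0.0505 and 0.0515). No other marker list passed between knockout and control. In marrow the camera adjusted p was 0.187 for B lineage, 0.581 for neutrophil, 0.746 for monocyte, 0.187 for osteoclast, 0.628 for erythroid, 0.71 for endothelial, 0.203 for smooth muscle (0.0352 without control replicate 1) and 0.628 for skeletal muscle genes. In GFP-positive bone cells it was 0.74 for B lineage and smooth muscle, 0.944 for neutrophil and Schwann cell, 0.799 for monocyte, osteoclast and erythroid, 0.998 for endothelial and 0.858 for skeletal muscle genes. In GFP-negative bone cells it was 0.928 for B lineage, neutrophil, monocyte, osteoclast and endothelial, 0.982 for erythroid and smooth muscle, 0.966 for skeletal muscle and 0.175 for Schwann cell genes. In marrow, beside the stroma and fibroblast lists, summed smooth muscle markers, mostly Acta2, were 1730 ± 1150 CPM of the library total in control and 621 ± 147 CPM in knockout libraries, and osteoclast markers, mostly Ctsk, were 766 ± 102 and 459 ± 204 CPM. Neutrophil markers summed to at most 76.4 ± 47.8 CPM and erythroid markers to at most 230 ± 251 CPM in any group. The 3 megakaryocyte genes measured, too few for camera, all rose in marrow (3 adjusted over the list alone), but only 1 of 3 without knockout replicate 2 and 2 of 3 without control replicate 1 or 2. Their sum in knockout replicate 2 was 262 CPM, against 2.45 and 3.77 CPM in the other knockout and 2.58 to 4.89 CPM in the control libraries. The T and NK list had 2 genes measured and summed to at most 1.63 ± 0.90 CPM.

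The knockout effect was then compared between subsets by an interaction term, without the pairing of same-number libraries. Cartilage genes separated the bone subsets: Col2a1 rose in GFP-positive cells (1.64 ± 0.16) and was at -0.22 ± 0.16 in GFP-negative cells, where it passed as lower after the length correction (-0.65, edgeR adjusted p = 0.00354) and with library totals (-0.48, edgeR adjusted p = 0.00664). Acan, plotted with it, was at 0.13 ± 0.14 in GFP-negative cells (edgeR adjusted p = 0.47) and at -0.66 after the length correction (edgeR adjusted p = 0.000699). Of 19 chondrocyte genes, 17 had a higher knockout effect in GFP-positive than in GFP-negative bone cells and none a lower one, with a median difference of 1.57 (18 adjusted over the list alone; camera adjusted p = 2.96e-57, and 0.000386 with an estimated correlation). Of the marker lists, Schwann cell genes had a higher effect in GFP-positive cells (2 of 6 passed; camera adjusted p = 0.00633, and 0.0716 with an estimated correlation). Hmgcs1, an enzyme of cholesterol synthesis, had effects of 1.63 and 0.01 and a difference of 1.62 ± 0.12. Lss, a later enzyme of that pathway, differed by 1.63 ± 0.14, Bdkrb1, a bradykinin receptor, by 2.22 ± 0.21, Hist1h2bc by 2.45 ± 0.21, and Enpp2, which makes lysophosphatidic acid, by 1.64 ± 0.14. In this comparison 772 genes had a higher and 172 a lower effect in GFP-positive cells, 944 in all (edgeR quasi-likelihood interaction test, two-sided, BH-adjusted p under 0.05). The share higher was 81.8%, and it was 70.7% with RLE factors, 61.4% with DESeq2 and 62.2% with library totals, which moved the median gene by -0.14.

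Bone formation genes separated the GFP-negative bone subset from marrow. Of 20 osteoblast genes, 15 had a higher effect in GFP-negative bone cells and none a lower one, with a median difference of 1.48 (18 adjusted over the list alone; camera adjusted p = 2.92e-26, and 0.0148 with an estimated correlation). Of 17 fibroblast genes, 10 had a higher effect and none a lower one (13 adjusted over the list alone; median 1.67; camera adjusted p = 7.66e-18, and 0.0148 with an estimated correlation). Of 16 glycolysis genes, 9 had a lower effect and 1 a higher one (10 and 2 adjusted over the list alone; median -0.84; camera adjusted p = 2.89e-16, and 0.0121 with an estimated correlation). Smooth muscle and pericyte markers went the same way as the osteoblast and fibroblast lists, with none of 7 past the gene test (median 1.80; camera adjusted p = 0.0227, and 0.329 with an estimated correlation). Mmp2, a matrix protease, had effects of 0.45 in GFP-negative bone and -1.53 in marrow, a difference of 1.98 ± 0.17. The effect of Mmp2 in bone lost its call with library totals (0.21, edgeR adjusted p = 0.166). Bnip3 (-2.34 ± 0.19), a mitophagy receptor induced by hypoxia, the glycolytic enzyme gene Aldoa (-1.45 ± 0.12), Arxes2 (-3.19 ± 0.29) and the sterol enzyme gene Sc5d (-1.65 ± 0.15) had lower effects in bone. Of 1209 genes that passed, 696 had a higher and 513 a lower effect in bone (edgeR quasi-likelihood interaction test, two-sided, BH-adjusted p under 0.05). The share higher was 57.6%, but 70.7% with RLE factors and 10.9% with library totals, which moved the median gene by -0.37.

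The GFP-positive bone subset and marrow also differed in bone formation genes. Of 11 osteocyte genes, 8 had a higher effect in bone and none a lower one, with a median difference of 2.24 (9 adjusted over the list alone; camera adjusted p = 5.63e-13, and 0.0158 with an estimated correlation). Of 20 osteoblast genes, 16 had a higher effect in bone and none a lower one (17 adjusted over the list alone; median 1.61; camera adjusted p = 5.38e-15, and 0.0496 with an estimated correlation). Marker lists that went the same way were smooth muscle (3 of 7 higher; camera adjusted p = 0.00287), B lineage (2 of 4; 0.00486) and Schwann cell genes (3 of 6; 0.00486), at camera adjusted p = 0.27, 0.0496 and 0.0541 with an estimated correlation. Alpl had effects of 0.63 in bone and -1.43 in marrow, a difference of 2.06 ± 0.16. Timp1 differed by 2.98 ± 0.20, with effects of 0.59 and -2.39, the first of which lost its call with library totals (0.21, edgeR adjusted p = 0.188). Nt5e, the ectonucleotidase CD73, differed by 2.77 ± 0.19, the cholesterol synthesis enzyme gene Sqle by 2.25 ± 0.16, and Map7d1 by 1.73 ± 0.13. Of 2853 genes that passed, 1674 had a higher and 1179 a lower effect in bone (edgeR quasi-likelihood interaction test, two-sided, BH-adjusted p under 0.05). The share higher was 58.7%, and 13.5% with library totals, which moved the median gene by -0.52. Regrouping the libraries could not test the 3 interaction counts, as the closing section reports.

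**Figure D4:**
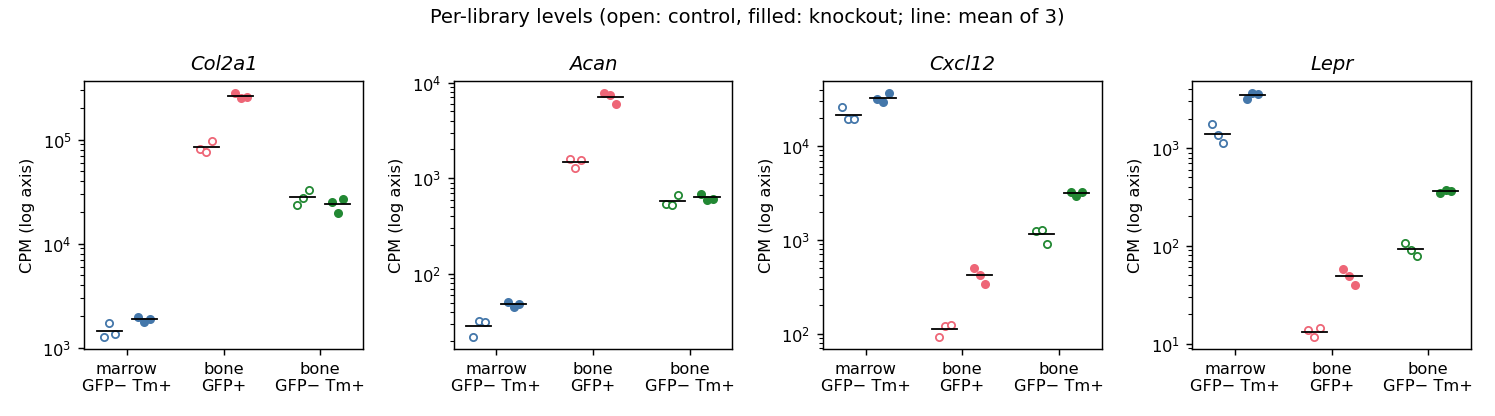
Col2a1, Acan, Cxcl12 and Lepr in CPM (log axis) in each library, by subset, with open points for control, filled points for knockout and a line at the mean of 3. In GFP-positive bone cells Col2a1 went from 84700 to 264000 CPM and Acan from 1470 to 7020 CPM, and in GFP-negative bone cells Cxcl12 went from 1150 to 3130 CPM and Lepr from 91.8 to 364 CPM (means, control first).

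Control libraries were compared between subsets to show how the sorted cells differ without the knockout. The pairing of same-number libraries was left out of these tests, except where a block is named. Within bone, GFP-positive cells held more cartilage and glycolysis transcripts than GFP-negative cells and less of the osteoblast, stroma and fibroblast ones. The osteoblast call was lost with an estimated correlation (camera adjusted p = 0.0561). Col9a3, a cartilage collagen gene, was 1.82 ± 0.12 higher on the log2 scale, Sox9, the master regulator of cartilage, 1.61 ± 0.10 higher, Pgk1 1.73 ± 0.10 and Ldha 1.52 ± 0.09 higher. The collagen genes Col1a1 (-2.68 ± 0.22) and Col1a2 (-2.66 ± 0.20), Cxcl12 (-3.37 ± 0.18) and Igf1 (-3.86 ± 0.18) were lower. By the naming rule Ddx25 (3.27 ± 0.37), Dlx2 (3.13 ± 0.38) and Stra6 (3.12 ± 0.62), a retinol transporter gene, led the higher genes, and Abcc9 (-6.42 ± 0.39), a potassium channel subunit gene, Cadps2 (-6.30 ± 0.56) and Fmo2 (-4.99 ± 0.64) the lower ones. Of 19 chondrocyte genes 18 were higher, and all 16 glycolysis genes were higher. Of 20 osteoblast genes 17 were lower and 1 higher, of 18 stroma genes 17 lower and 1 higher, of 17 fibroblast genes 15 lower, of 15 regulators of blood cells 13 lower, of 12 Wnt antagonists 9 lower and 2 higher, of 12 Wnt targets 6 lower and 1 higher, of 21 adipocyte genes 8 lower and 4 higher, and of 11 osteocyte genes 7 lower and 2 higher. Of 18 immediate early genes 9 were higher. Adjusted over the list alone these were 19 chondrocyte genes higher, 14 regulators and 9 adipocyte genes lower, and 10 immediate early genes higher with 1 lower. The other counts were the same adjusted over the list alone.

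For GFP-positive against GFP-negative control bone cells the edgeR camera adjusted p was 5.83e-28 for chondrocyte, 4.66e-23 for glycolysis, 5.85e-32 for stroma, 7.83e-10 for fibroblast, 1.85e-15 for regulators of blood cells, 0.000468 for Wnt antagonists, 0.000235 for Wnt targets and 0.00257 for adipocyte genes. These 8 calls held with an estimated correlation (camera adjusted p of 0.0373 or less). The osteoblast (camera adjusted p = 2.94e-11), osteocyte (0.0429), immediate early (0.019), osteoclast (0.046, 2 of 5 lower) and smooth muscle (0.00164, 4 of 7 lower) calls were lost, at camera adjusted p = 0.0561, 0.31, 0.675, 0.165 and 0.2 with an estimated correlation. The osteocyte call was also lost without GFP-positive control replicate 1 or 3 (camera adjusted p = 0.064 and 0.0694), and the osteoclast call without any 1 of the 6 libraries (0.0565 to 0.102) and without a filter on low counts (0.0535). With the replicate number as a block the osteocyte and osteoclast calls were lost (camera adjusted p = 0.0833 and 0.0533) and the interferon list passed, lower in GFP-positive cells (0.0187). Of 6203 genes that passed, 2820 were higher in GFP-positive and 3383 in GFP-negative cells (edgeR quasi-likelihood test, two-sided, BH-adjusted p under 0.05). The share higher was 45.5%, and 62.2% with library totals, which moved the median gene by 0.19, and 57.2% after the length correction. Lists that did not pass were cAMP (camera adjusted p = 0.54), cell cycle (0.89), oxidative phosphorylation (0.188), p53 (0.179) and interferon genes (0.107, with 5 of 16 lower and a median of -1.64, but 0.0492 with a median of -1.58 after the length correction), B lineage (0.188), neutrophil (0.815), monocyte (0.917), erythroid, endothelial (both 0.89), skeletal muscle (0.798) and Schwann cell genes (0.107).

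GFP-negative bone cells carry the same colours as the marrow cells and differed from them in 11 of 25 lists in controls, and in 6 with an estimated correlation. All 19 chondrocyte genes were higher in bone (Col9a3 4.63 ± 0.14; Hapln1 4.62 ± 0.14) and all 18 stroma genes lower (Cxcl12 -4.25 ± 0.19; Lepr -3.93 ± 0.17; Esm1 -4.67 ± 0.17). Of 21 adipocyte genes 17 were lower and 1 higher, with Adipoq, adiponectin, at -4.47 ± 0.22 and Lpl at -4.01 ± 0.17. Of 17 fibroblast genes 14 were higher and 1 lower (Postn 4.08 ± 0.20; Dpt 6.17 ± 0.50). Of 20 osteoblast genes 12 were higher and 1 lower (Alpl 1.19 ± 0.11; Smpd3 1.70 ± 0.20), and of 11 osteocyte genes 8 were higher (Fbln7 4.14 ± 0.15; Pdpn 2.81 ± 0.19). Of 16 glycolysis genes 13 were higher (Pkm 1.81 ± 0.10), of 18 oxidative phosphorylation genes 12 were higher, and of 15 regulators of blood cells 11 were lower and 3 higher. By the naming rule Angptl7 (6.85 ± 1.28), Ostn (6.73 ± 0.30), which encodes osteocrin, and Kera (6.48 ± 1.08) led the higher genes, and Adamdec1 (-6.38 ± 0.61), Cfd (-6.20 ± 0.92), the complement factor adipsin, Cbln1 (-5.81 ± 0.17) and Timp4 (-5.60 ± 0.39) the lower ones. Adjusted over the list alone, 15 osteoblast, 9 osteocyte, 15 fibroblast and 14 glycolysis genes were higher and 2 adipocyte genes were higher, and the other counts were the same.

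For GFP-negative bone against marrow the edgeR camera adjusted p was 3.85e-96 for chondrocyte, 5.84e-67 for stroma, 2.26e-14 for adipocyte, 2.49e-14 for regulators of blood cells, 4.21e-13 for glycolysis and 5.18e-07 for osteocyte genes, and these held with an estimated correlation (camera adjusted p of 0.0185 or less). The fibroblast (5.11e-08), osteoblast (0.0121), oxidative phosphorylation (0.0418), smooth muscle (0.00729, 6 of 7 lower) and Schwann cell (0.0138, 3 of 6 higher and 1 lower) camera calls were lost, at adjusted p = 0.0849, 0.602, 0.613, 0.389 and 0.0921 with an estimated correlation. The Schwann cell call also ended without a filter on low counts (camera adjusted p = 0.165). The oxidative phosphorylation call also ended after the length correction (camera adjusted p = 0.249, and 0.149 with the exon length of the count files), with RLE factors (0.0703), in a fit of only the libraries compared (0.0655) and without marrow replicate 1, bone replicate 1 or bone replicate 3 (0.0633, 0.0508 and 0.06). Of 6098 genes that passed, 3275 were higher in bone and 2823 lower (edgeR quasi-likelihood test, two-sided, BH-adjusted p under 0.05). The share higher was 53.7%, and 27.6% with library totals, which moved the median gene by -0.28. Lists that did not pass were cAMP (camera adjusted p = 0.189, and 0.0252 without marrow replicate 3), immediate early (0.0863, and 0.00168 without marrow replicate 3 and 0.0441 without bone replicate 2), Wnt targets (0.252), Wnt antagonists (0.334), cell cycle (0.126), p53 (0.216), interferon (0.0881, and 0.0476 without bone replicate 2), B lineage (0.197), neutrophil, osteoclast and skeletal muscle (each 0.611), monocyte (0.603), erythroid (0.216, and 0.0139 without bone replicate 2) and endothelial genes (0.225). With the replicate number as a block the interferon list passed, lower in bone (camera adjusted p = 0.012).

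GFP-positive bone cells differed most from marrow in number of genes in controls. Of 9743 genes that passed, 4625 were higher in bone and 5118 lower (edgeR quasi-likelihood test, two-sided, BH-adjusted p under 0.05). All 19 chondrocyte genes (Col9a3 6.45 ± 0.15; Sox9 4.86 ± 0.12) and all 16 glycolysis genes (Pgk1 3.34 ± 0.11; Ldha 3.01 ± 0.10) were higher, and all 18 stroma genes lower (Cxcl12 -7.62 ± 0.22; Lepr -6.73 ± 0.19). Of 21 adipocyte genes 16 were lower and 2 higher (Adipoq -7.65 ± 0.26), of 15 regulators of blood cells 12 were lower and 3 higher, of 20 osteoblast genes 14 were lower and 3 higher, of 18 immediate early genes 10 were higher, and of 18 oxidative phosphorylation genes 14 were higher and 1 lower (15 and 1 adjusted over the list alone). The counts of the other lists named here were the same adjusted over the list alone. By the naming rule Mcoln3 (8.11 ± 0.60) was among the largest of the higher genes, and Nrarp (-8.60 ± 0.95) and Cap2 (-8.34 ± 1.31) among the largest of the lower ones. Ptchd1 was at 5.97 ± 1.96 CPM in marrow and at 0 in all 3 GFP-positive bone libraries, at least 41.4-fold lower by the same floor.

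For GFP-positive bone against marrow the edgeR camera adjusted p was 9.95e-64 for chondrocyte, 1.84e-51 for stroma, 2.68e-23 for glycolysis, 9.91e-16 for regulators of blood cells and 1.27e-08 for adipocyte genes, and these held with an estimated correlation (camera adjusted p of 0.00442 or less). The osteoblast (0.0264), immediate early (0.0208), oxidative phosphorylation (0.041), smooth muscle (0.00345, 6 of 7 lower) and Schwann cell (0.0325, 3 of 6 higher and 1 lower) camera calls were lost, at adjusted p = 0.663, 0.663, 0.663, 0.372 and 0.211 with an estimated correlation. The Schwann cell call also ended without a filter on low counts (camera adjusted p = 0.2). The oxidative phosphorylation call also ended after the length correction (camera adjusted p = 0.175, and 0.0633 with the exon length of the count files), in a fit of only the libraries compared (0.075) and without bone replicate 2 (0.0554). Lists that did not pass were osteocyte (camera adjusted p = 0.198), cAMP (0.252), Wnt targets (0.168), Wnt antagonists (0.17), fibroblast (0.975; median 0.76, test down), cell cycle (0.288), p53 (0.152), interferon (0.0594, but 0.0367 after the length correction and 0.049 without marrow replicate 1), B lineage (0.978), neutrophil and skeletal muscle (both 0.664), monocyte (0.696), osteoclast (0.436), and erythroid and endothelial genes (both 0.472). With the replicate number as a block the interferon list passed, lower in bone (camera adjusted p = 0.00538).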

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

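Of the tests in this part, the list tests of the interactions, the checks of how regrouped libraries were made up and how they part pairs, the GC check, the share of calls left after the length correction, the carry-over test and the length tests of the stroma genes and of AI506816 were chosen after the result was seen.

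The knockout effect differed between subsets by the interaction term of the edgeR model in 944 genes for GFP-positive against GFP-negative bone, in 1209 for GFP-negative bone against marrow and in 2853 for GFP-positive bone against marrow. Between the bone subsets the knockout effect differed by 1.62 for Hmgcs1, 2.22 for Bdkrb1, 2.45 for Hist1h2bc, 1.64 for Enpp2 and 1.63 for Lss on the log2 scale, higher in GFP-positive cells. Between GFP-negative bone and marrow it differed by -2.34 for Bnip3, -1.45 for Aldoa, 1.98 for Mmp2, -3.19 for Arxes2 and -1.65 for Sc5d. Between GFP-positive bone and marrow it differed by 2.98 for Timp1, 2.77 for Nt5e, 2.25 for Sqle, 2.06 for Alpl and 1.73 for Map7d1. The median differences were 1.57 for the chondrocyte list between the bone subsets, 1.48 for the osteoblast list between GFP-negative bone and marrow, and 2.24 for the osteocyte list between GFP-positive bone and marrow.

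Splits of the libraries show how often other groupings give as many calls. For the interactions, 100 of the 200 possible splits were drawn. As many genes came from 9 for the bone subsets (944 real, highest other 9135), 9 for GFP-negative bone against marrow (1209, 4837) and 8 for GFP-positive bone against marrow (2853, 5327), the real split included. The other splits with as many genes, 8, 8 and 7 of them, all kept the genotype labels whole in at least 1 subset. Their contrasts hold the knockout effect. Splits that mixed the genotypes in both subsets (at most 0, 1 and 0 genes) hold it as spread. Neither kind shows whether the interaction counts arose by chance. For the 6 comparisons of groups of 3, only 10 splits exist, too few for a share under 0.05. The real split alone, 1 of 10, gave as many genes in each, with 7425 in marrow (highest other 2), 7953 in GFP-positive bone (0), 7315 in GFP-negative bone (0), 6203 between the bone subsets of controls (0), 6098 for GFP-negative bone against marrow (0) and 9743 for GFP-positive bone against marrow (0). Gene lists were called as often in 2 of 10 splits for marrow (12 real, highest other 12), 6 for GFP-positive bone (8, 14), 7 for GFP-negative bone (9, 12), 1 for the bone subsets of controls (13, 12), 7 for GFP-negative bone against marrow (11, 16) and 4 for GFP-positive bone against marrow (10, 12). Where 6 or 7 splits did, these list counts do not set the real grouping apart. Elsewhere 10 splits are too few. In each control comparison 4 of the 10 splits, the real one included, part all 3 same-number pairs. The others of that kind gave 0 genes and at most 12, 16 and 12 lists in that order. The rest gave 0 genes and at most 11, 14 and 11 lists.

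The first pattern weighed is the dependence of the knockout fold changes on transcript length. As the whole cause of the calls it is argued against, since at least 63% of the calls in each subset passed in the same direction after its removal. GC content is argued against as well, with a correlation of at most 0.062 with the fold change. A difference of RNA or library quality between the genotypes is consistent with the slope of at least 0.273 per doubling among 1839 genes with similar levels in the 3 control subsets. It cannot be told apart from an effect of the knockout on long transcripts, because the trend goes with the genotype in every subset.

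The second pattern is the rise of stroma genes in both knockout bone subsets, for which carry-over of marrow stromal cells is a candidate explanation, while length bias is argued against by a corrected median of at least 1.26 in both. The stroma list genes stood at a median of 7.54% of their marrow level in GFP-negative and 1.49% in GFP-positive control bone cells. In knockouts the medians were 10.4 and 1.61% of the knockout marrow level. The shift of the stroma list relative to marrow was 0.51 in GFP-negative and 0.55 in GFP-positive bone cells. Marrow-enriched genes outside the list had median shifts of 0.47 ± 0.55 and 0.49 ± 0.87 (SD over genes). Of these genes, 6.3% of 63 and 19.9% of 226 departed by over 1 log2 unit from the list's shift. Between knockout and control bone cells 63.5 and 46.9% of them rose and 1.6 and 2.7% fell, in that order. Carry-over needed under 10% in both subsets and over 50% would have argued against it, so it cannot be told apart from a change within the bone cells. The GFP-negative bone gate has the colours of the marrow cells and would not remove them, whereas the GFP-positive gate would, and 8 of the 18 genes are also in the adipocyte or blood cell lists.

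The third pattern is AI506816, a processed transcript (mm10 chromosome 5, 23698296 to 23712667, minus strand) at 0.152 to 0.479 CPM in the 9 control and 29.9 to 134 CPM in the 9 knockout libraries. Reads of a neighbour are argued against, since no tested gene within 100 kb was higher by more than 0.09 in all 3 subsets. Of the 65 tested genes within 5 Mb, 3.08% changed at least 2-fold in all 3 subsets, against 6.65% of all genes. A differing chromosome segment need not change its genes and stays open. Length bias is argued against by a smallest corrected log2 fold of 6.76. A difference between the strains or the constructs carried by the genotypes may act on this transcript alone and was not tested.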

How the results depend on the processing

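Depth sets the floor of 0.097 to 0.216 CPM. Simulations without a length trend recovered at most 47.8% of 2-fold knockout changes. Most real knockout calls were smaller, so that share need not hold here. Against a 1.5-fold change, a test chosen after seeing the data, calls fell to 2998 in marrow, 3835 in GFP-positive and 3034 in GFP-negative bone, 201, 331 and 785 for the interactions (bone subsets, GFP-negative bone with marrow, GFP-positive bone with marrow) and 2743, 2508 and 6209 for controls in that order, because the test asks for more. DESeq2 called 1420 genes for the interaction of the bone subsets. With library totals, also chosen after seeing the data, the interactions with marrow gave 3740 and 5677. The cause was not tested for these. With an estimated correlation 1, 2 and 3 lists were called in the knockout comparisons and 8, 6 and 5 in controls, because it widens the spread of a list, and fry called 19 lists in each control comparison with marrow, because it does not set a list against other genes. All other counts stayed within 1.5 times. Which side held more genes also turned in other settings. The share higher became 53.4% in marrow without a filter on low counts or with only the libraries compared and 56.8% against a 1.5-fold change, 49.4 and 48.3% in GFP-positive bone after the length corrections (transcript and exon length), and in GFP-negative bone 52.2% without the filter, 51.1% with only the libraries compared and 54.3% against a 1.5-fold change. In controls it became 55% with RLE factors, 53.2% with DESeq2, 52.1% without the filter and 57.8% with the exon length between the bone subsets. Between GFP-negative bone and marrow it became 49% with RLE factors, 49.3% with only the libraries compared and 48.4% against a 1.5-fold change, and between GFP-positive bone and marrow 50.3% with RLE factors, 50.6% without the filter and 53 and 53.1% after the length corrections.

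Without single libraries the calls ranged from 6489 to 6858 in marrow, 7071 to 7530 in GFP-positive and 6391 to 6721 in GFP-negative bone, 664 to 855, 899 to 1244 and 2177 to 2772 for the interactions, and 5247 to 5602, 5012 to 5536 and 9082 to 9334 for controls. Lists ranged from 11 to 15, 8 to 8, 7 to 9, 11 to 12, 10 to 14 and 9 to 11. The lists that lost or gained a call without 1 library are named beside their results, as are those lost in other settings except the block within each genotype, given below. Without a filter on low counts camera also called, in the knockout, regulators of blood cells (adjusted p = 0.0452) and Wnt targets (0.0295) in marrow and cell cycle in GFP-positive bone (0.0122). In controls it called oxidative phosphorylation (0.00143) and interferon (0.00191) between the bone subsets, immediate early (0.00971), Wnt antagonist (0.0228), cell cycle (0.00234) and interferon genes (0.00832) between GFP-negative bone and marrow, and cell cycle (0.044) and interferon genes (0.000232) between GFP-positive bone and marrow. With only the libraries compared camera also called interferon genes in the 3 control comparisons (adjusted p = 0.014, 0.00051 and 0.000217) and Schwann cell genes between the bone subsets (0.026). With the exon length of the count files it called immediate early genes in GFP-negative bone (camera adjusted p = 0.0443) and interferon genes in GFP-positive against both other control subsets (0.0469 and 0.0353).

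Named genes lost a call in few settings, all chosen after seeing the data. These are Pth1r in both bone subsets (length corrections; with the exon length of the count files -0.25 and -0.28, edgeR adjusted p = 0.118 and 0.0864), Runx2 in both, Col1a2 in GFP-negative bone, and with library totals Alpl and Timp1 in GFP-positive and Mmp2 in GFP-negative bone. Against a 1.5-fold change Pth1r was lost in all 3 subsets (edgeR adjusted p = 0.221, 0.714 and 0.619), as were Aldoa in marrow, Alpl and Timp1 in GFP-positive bone and Mmp2 in GFP-negative bone. Acan in GFP-negative bone turned to -0.66 after the length correction, to -0.23 with the exon length and to -0.11 with library totals. Hmgcs1 there, near 0, turned to -0.23 with library totals, and ranged from -0.03 to 0.07 without single libraries. Col2a1 there passed only with the length corrections and library totals. The cause was not tested for these.

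The replicate numbers pair the subsets within a genotype, as described with the processing. Same-number correlations between knockout and control of a subset ran from -0.15 to 0.255. Over all 45 same-number pairs 22 correlations were over 0.1, and 17 of 18 libraries were closest to their own number. Y-linked genes summed to 84.5 to 169 CPM in replicates 1 and 2 and to 1.19 to 3.89 CPM in replicate 3 of all groups. Sex thus goes with the number. With the number as a block the calls were 7593, 8124 and 7467 for the knockout, 1009, 1305 and 3046 for the interactions and 6341, 6249 and 9843 for controls, and the lists 12, 8, 9, 12, 12 and 11. This block changed no list call of the 6 comparisons with list counts, and no call of a named gene, other than those given beside the control results. With a block within each genotype, chosen after seeing the data, the interactions gave 1342, 1604 and 3449 and the controls 6733, 6582 and 10076 genes. It lost the same osteocyte and osteoclast calls (camera adjusted p = 0.0805 and 0.0531), gave the same interferon calls (0.00118, 0.000872 and 0.000178), and added Schwann cell genes between the bone subsets (0.0485) and immediate early genes between GFP-negative bone and marrow (0.0382). Between knockout and control it ended the osteoblast call in GFP-negative bone (camera adjusted p = 0.0511) and added regulators of blood cells in marrow (0.0345), but there it takes out variation between libraries that the comparison rests on.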

Other observations

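The gene lists of this part, except the test of the second glucocorticoid list, and the comparison of the clock arms were chosen after results for some of their genes were seen.

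Of 20 genes of sterol synthesis, 13 rose and 3 fell in GFP-positive knockout cells (median 0.46), whereas 16 fell and none rose in GFP-negative cells (median -1.02) and 11 fell and 2 rose in marrow (median -0.76). Of the 20, 17 had a higher knockout effect in GFP-positive than in GFP-negative bone cells and none a lower one (median difference 1.44). Some of these genes had been seen, so no p is given for the full list. In controls all 20 were higher in GFP-positive than in GFP-negative bone cells (median 1.57) and than in marrow (median 2.97). With the genes that had been seen in the knockout comparisons left out, 13 of 16 still had a higher effect in GFP-positive bone cells (camera p = 1.16e-28, and 0.00012 with an estimated correlation). The medians and camera p were -0.80 and 5.22e-06 in marrow, 0.35 and 0.0834 in GFP-positive bone, and -1.07 and 1.76e-06 in GFP-negative bone (0.0465, 0.414 and 0.0335 with an estimated correlation). That shorter list was made after the full result, and not all of its genes were unseen in the control comparisons.

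Of 16 genes that respond to hypoxia, chosen after falls of Bnip3, Ndufa4l2, Fam162a and glycolysis genes had been seen, 12 fell and 3 rose in GFP-positive knockout cells (median -1.41), 8 fell and 3 rose in GFP-negative cells (median -0.84), and 6 fell and 5 rose in marrow (median 0.05). Since the list was made from what it describes, these counts are no test of the group and no p is given.

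A hypothesis from the rise of Zbtb16 and Per1 is that genes that respond to glucocorticoids are higher in the knockout. A first list was made from such genes after they were seen to rise, and its 10 of 10 members higher in each subset only restate that. The test is a second list of 19 genes, whose values had not been looked at, which had 13, 8 and 7 members higher and 1, 0 and 1 lower, with a camera p of 4.14e-06, 0.00626 and at most 0.0162 in that order (0.00181, 0.0378 and 0.0644 with an estimated correlation). The second list is consistent with the hypothesis with the preset correlation, is not past 0.05 in GFP-negative bone with an estimated one, and says nothing of hormone levels. A shift of clock phase cannot be told apart from it, because the medians of the evening and morning arms of the clock differed by 0.27 ± 0.65, 0.37 ± 0.69 and 0.07 ± 0.67 (SE from 2000 resamples of the genes), too wide to decide. Evening-arm genes rose in 7, 7 and 6 of 10 cases (camera p = 9.47e-05, 0.0124 and 0.00215, and 0.042, 0.154 and 0.0928 with an estimated correlation), and morning-arm genes in 3 of 5 in each subset (0.14, 0.319 and 0.158), on arms chosen after Per1 was seen. Handling or time of collection that differed between the genotypes may act in the same direction and was not tested.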
